A study of Mus musculus with 14 samples.

How the data were processed

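The data were CUT&RUN peak lists from 14 libraries of mouse Th1 cells, 8 groups formed by antibody (H3K27ac, CTCF, ETS1, IgG) and genotype (WT or Ets1-SE-KO), as given in the sample titles. Per the labels' protocols, the libraries were sequenced as paired ends of 38 bp or 61 bp on 2 instruments, without a statement of which library was run on which. Reads were aligned with BWA to GRCm38, per the submitters' processing notes. The peak names inside the deposited files carry the MACS2 naming of broad peaks, and each list belongs to a single library. The versions, the options of the peak caller, the use of a control library in calling, and any removal of duplicates or of blacklisted regions are not given in the sources used here.

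Each deposited list has 9 columns without a header. Per the file layout, the authors' score is a whole number derived from the q-value, the fold value is a ratio of enrichment over background, and the last 2 columns are −log10 p and −log10 q as the authors' peak caller wrote them. These per-peak values belong to the authors, were made within a library, and were used only to rank peaks inside their own list. The lists hold no read counts, so depth per library is unknown, and no interval or floor that needs depth is given. A longer list or wider peaks can follow from deeper sequencing or lower background as well as from more occupied chromatin. Only chromosomes 1 to 19, X and Y were kept.

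Peaks of the 4 libraries of an antibody were merged where they overlapped by at least 1 bp. A merged region was WT-only when both WT libraries and neither KO library had a peak in it, KO-only in the opposite case, and shared when all 4 had a peak. The numbers were set beside the 2 splits of the same libraries that mix genotypes. Covered length is the sequence under peaks. Ratios of covered length were log2 of the KO mean over the WT mean after adding 1 kb to each, and ratios of peak numbers after adding 1 peak. The Ets1 window was chromosome 9 from 32000000 to 34000000, ranked among 2 Mb tiles with at least 50% of its WT peak number, and bins of 25 kb were ranked by the difference in mean covered length among bins where both libraries of a genotype exceeded both of the other. Exact two-sided permutation tests compared covered length and peak number per library. Agreement between lists was the shared length as a percentage of the joint length.

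Genes and coordinates came from an NCBI RefSeq table of GRCm38.p6 with 21883 protein-coding genes on the chromosomes used. Each gene was given flanks of 10 kb. The 17 gene lists, of 213 different genes, were fixed before the data were examined, all members were matched by symbol or synonym, and 4 genes are in more than 1 list. The lists are the Ets1 locus, Th1, Th2, Th17, Treg, Tfh, T cell identity, naive and memory T cell, T cell activation, ETS family and housekeeping genes, and markers of B, myeloid, CD8 T, NK, erythroid and non-haematopoietic cells. A list's percentage of WT-only or KO-only regions was placed among 10000 random lists of protein-coding genes matched on the number of regions, and its median log2 covered length, a measure added after the data were examined, among 10000 lists matched on covered length, with ties counted as 50%. Regions were counted per gene, so a region in the windows of neighbouring genes counts for each of them. For H3K27ac this gave 997 WT-only and 3038 KO-only over all genes, against 985 and 2588 distinct regions. Lists with neighbouring members can thus count a region repeatedly, and the effect on their percentiles was not examined. These percentiles describe the libraries and are not p-values. ETS1 regions called in both libraries of a genotype were compared with random placements on the same chromosomes, 100 times with a fixed seed. Intervals of shares are exact Clopper-Pearson intervals at 95% and, as Fisher's exact test, treat regions as independent, which they are not.

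The genes named in the text follow a rule fixed beforehand. It takes the genes of the Ets1 locus list always, for each antibody up to 10 list genes with the most WT-only and up to 10 with the most KO-only regions, up to 10 WT-only and 10 KO-only regions with the best rank in the weaker of their 2 libraries, with the nearest protein-coding gene, and the 10 H3K27ac bins with the greatest difference in each direction. Other genes are marked in the text as picked after their values were seen. Some genes that the rule takes are not reported here, although they stay in the counts and medians of their lists.

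The plan was departed from in the following ways. The gene table has no strand or exons, so windows of 2 kb around both ends of a gene replaced windows around transcription starts, peaks were placed only near gene ends, in gene bodies or between genes, and the nearest gene replaced the nearest start. A genome sequence was not used here, so the intended motif comparison was not run. Intersections were computed with Python code in place of bedtools.

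The alternatives set out before the data were examined were the same number of top-scored peaks in each library, the top-scored 50% of each list, an overlap of at least 50% of the shorter peak, merging of peaks up to 500 bp apart, removal of peaks overlapping an IgG peak, removal of each library in turn, bins of 10 and 50 kb, flanks of 50 kb, windows of 5 kb at gene ends, windows of 1 kb for location, ETS1 peaks called in either WT library, and peak number in place of covered length. The code was tested on simulated lists of 35340 regions made from the H3K27ac regions. It found 200 of 200 WT-only and 300 of 300 KO-only regions. It also ranked first 20 of 20 tiles of 2 Mb whose shared regions had been made WT-only. The simulated peaks had slightly shifted ends and were not split, so this checks the code and not its accuracy on the real lists. Of 400 random lists without an effect, 15 lay above the 95th percentile for WT-only regions, 17 for KO-only regions and 42 for covered length, and 36 lay below the 5th percentile for covered length, so percentiles of covered length are too extreme at both ends. The number of such lists was raised to this after a smaller first run had left the check imprecise, with more lists above the 95th percentile than chance gives. All 5 lists given extra WT-only regions lay above the 95th percentile. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.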

Results

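CUT&RUN, in which an antibody-tethered nuclease releases the DNA around its target, was used to map the acetylated histone mark H3K27ac, the chromatin architectural protein CTCF and the transcription factor ETS1 in mouse Th1 cells. The cells were naive CD4 T cells from spleen, cultured for 6 days with 10 ng/mL IL-12 and 1 ng/mL IL-2. Wild-type (WT) cells were compared with cells of a strain labelled Ets1-SE-KO (KO), with 2 libraries per antibody and genotype. The titles describe the 2 WT libraries as technical replicates of 1 biological replicate and the 2 KO libraries as 2 biological replicates, so an SD over the WT libraries is a technical spread and an SD over the KO libraries a spread between biological replicates. The names of the deposited lists number the 2 CTCF libraries of WT differently, which leaves it uncertain whether these are technical replicates, while the WT libraries of H3K27ac and of ETS1 share a number within each antibody, and the titles were followed. A control antibody (IgG) was run in 1 library per genotype. Each library is represented by its own list of called peaks. Such lists hold no read counts, so the depth of each library is unknown, and all values below are numbers of peaks or lengths of sequence covered by them.

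For H3K27ac, 24711 and 24581 peaks covered 21.8 and 21.3 Mb in the WT libraries, and 26465 and 28647 peaks covered 28 and 28.5 Mb in the KO libraries. Covered length was thus 1.31 times as high in KO for H3K27ac, at 28.3 ± 0.372 Mb against 21.5 ± 0.364 Mb (SD, 2 libraries each, from 1 biological replicate in WT). For CTCF the ratio was also 1.31, at 23.4 ± 1.53 Mb from 40502 and 39345 peaks in KO against 17.9 ± 0.689 Mb from 33144 and 31368 peaks in WT. The ETS1 lists were uneven within genotypes, with 14013 and 23419 peaks in WT and 40705 and 9344 in KO. IgG gave 2 peaks in WT and 285 in KO. With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333, which both the H3K27ac and the CTCF covered lengths reached, while ETS1 gave an exact p of 1. This test counts the 2 WT libraries as separate replicates although the titles give 1 biological replicate. No region or gene was tested between the genotypes, and the comparisons below describe these libraries.

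The locus named in the strain label was examined first, to see where the marks at Ets1 differed between the genotypes. It was also asked how far the rest of the genome differed as much. By the label, an element at this locus was knocked out. Its coordinates are not given, so calls missing here may be the engineered change itself. Ets1, which encodes a transcription factor of the ETS family, lies on chromosome 9 from 32636241 to 32757820 (GRCm38). H3K27ac peaks covered 45.4 ± 1.72 kb of the gene in WT and 23.8 ± 0.631 kb in KO (SD, 2 libraries each, from 1 biological replicate in WT), which is 52.5% of the WT length. Downstream of the gene, H3K27ac was called in WT only, in 8 regions between 32906098 and 32943055, the nearest of them 148277 bp beyond the gene's end. The widest of these, from 32922352 to 32930506, spanned 8155 bp. No H3K27ac peak was called there in either KO library. These 8 regions lie outside any protein-coding gene.

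Between 32746522 and 32940318, a stretch of 193797 bp that begins inside Ets1, none of the KO libraries of any antibody had a peak. H3K27ac covered 26420 and 25692 bp of it in the WT libraries. Most of the stretch had few WT peaks as well. Between 32750791 and 32900033 these were an H3K27ac peak of WT replicate 1 and an ETS1 peak of WT replicate 2. Among 80330 stretches of the genome without a KO peak, ranked by the lower of the 2 WT H3K27ac lengths, this stretch ranked 1. The stretch at rank 2 was also inside Ets1, from 32710314 to 32717375, with at least 5765 bp of WT H3K27ac. The stretch at rank 3, with 5187 bp, lay on chromosome 15 from 64042471 to 64053360, nearest to Cyrib. This ranking was chosen after the lists had been examined. At the distal edge, the CTCF regions from 32940265 to 32941867 and from 32942854 to 32943085 were called in all 4 CTCF libraries.

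**Figure D1:**
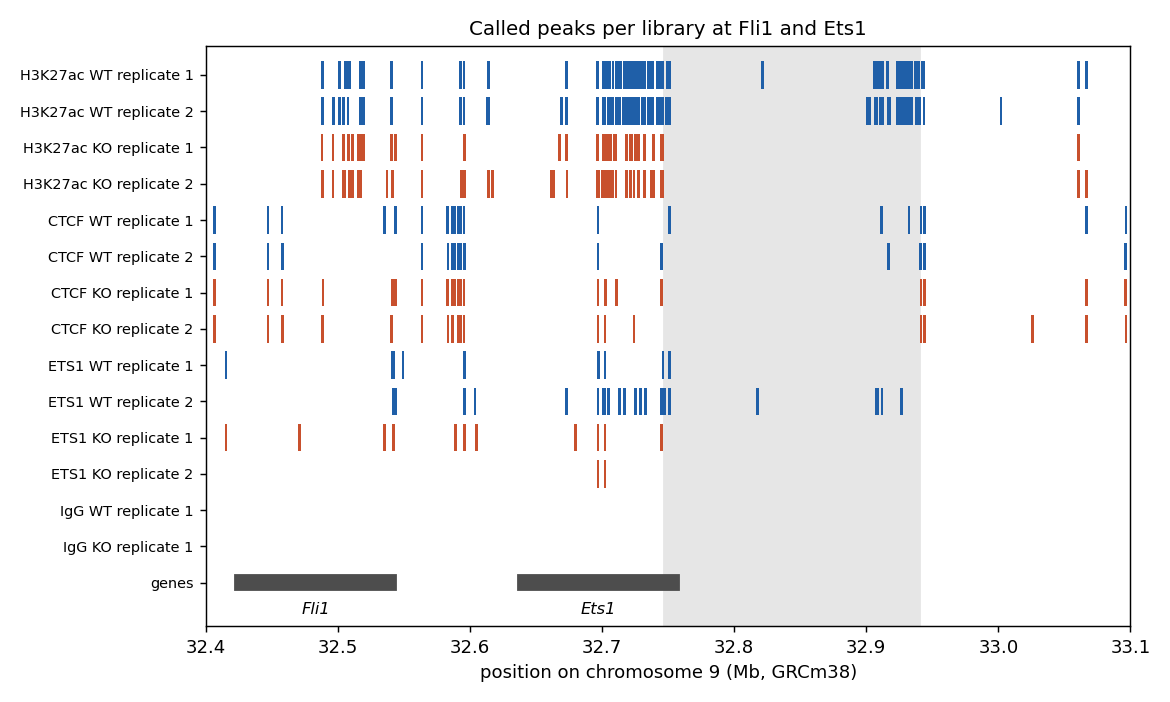
Called peaks of the 14 libraries on chromosome 9 between 32.4 and 33.1 Mb (GRCm38), each row a library, each box a peak drawn to scale with a minimum width so that short peaks stay visible. Blue is WT, orange is KO, dark bars are genes, and the grey band is the stretch of 193797 bp without a KO peak, where the H3K27ac peaks of both WT libraries are seen.

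In the 2 Mb window from 32000000 to 34000000, H3K27ac covered 83.9 ± 1.86 kb in WT and 34.7 ± 0.298 kb in KO, a log2 ratio of -1.25. Of 431 tiles of that size with enough WT peaks to compare, this was the lowest ratio, and the median tile stood at 0.37. The tile with the next lowest ratio, on chromosome 17 from 82000001 to 84000000, stood at -0.36. ETS1 peaks in the window covered 9.19 ± 6.48 kb in WT and 3.89 ± 2.20 kb in KO, a log2 ratio of -1.06 that ranked 2 of 710 tiles, but the spread between the ETS1 libraries was wide, and the ratio was -1.59 without WT replicate 1, -0.20 without WT replicate 2, -1.61 without KO replicate 1 and -0.66 without KO replicate 2. CTCF covered 9.94 ± 0.963 kb in WT and 13.8 ± 0.131 kb in KO, a log2 ratio of 0.43 against a median tile of 0.37. With the same number of peaks per library the window's CTCF ratio was lower, as given below with the processing. The number of H3K27ac peaks differed less than their length, with 40 per library in WT and 30.5 in KO, a log2 ratio of -0.38. IgG gave no peak in the window.

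**Figure D2:**
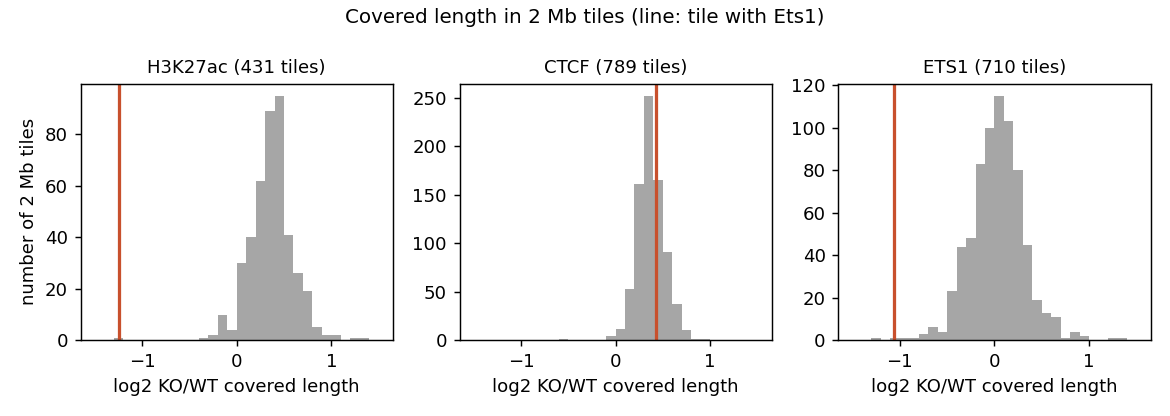
Distribution of the log2 ratio of KO to WT covered length (horizontal axis, 1 kb added to each mean) over 2 Mb tiles of the genome (vertical axis, number of tiles) for H3K27ac, CTCF and ETS1. The vertical line is the tile that holds Ets1, which lies at -1.25 for H3K27ac, 0.43 for CTCF and -1.06 for ETS1.

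Within Ets1, ETS1 protein was called in all 4 libraries from 32695696 to 32697919 and from 32700631 to 32702198, and in WT only from 32744830 to 32745679 and from 32750074 to 32750555. The neighbouring gene Fli1, which encodes another ETS factor, had 8.03 ± 0.675 kb of H3K27ac in WT and 9.12 ± 0.385 kb in KO. CTCF peaks covered 0.905 ± 0.40 kb of Fli1 in WT and 3.24 ± 0.614 kb in KO, where CTCF covered length as a whole was 1.31 times as high. The KO-only CTCF regions in Fli1, from 32486888 to 32488054 and from 32539593 to 32541380, lay within H3K27ac regions called in all 4 libraries. The CTCF regions beginning at 32445744 and 32456369 were shared. Among the other genes of the region, H3K27ac covered 1.30 and 1.36 kb of Nfrkb, 1.69 and 2.34 kb of Prdm10, 1.62 and 1.65 kb of Zbtb44 and 0.183 and 0.374 kb of Aplp2 on average in WT and KO. Arhgap32, Kirrel3, Kcnj1, Kcnj5, Tmem45b, Barx2, St14 and Adamts15 carried no H3K27ac peak inside the gene in any library, although the 10 kb flanks of Kirrel3 held a WT-only region. Arhgap32 had CTCF peaks over 0.746 ± 0.0113 kb in WT and 2.24 ± 0.200 kb in KO.

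Across the genome in 25 kb bins, the 4 bins with the greatest excess of WT over KO H3K27ac all had Ets1 as their nearest gene. They began at 32925001, 32725001, 32900001 and 32700001 on chromosome 9, with mean differences of 14.0, 12.2, 11.4 and 8.74 kb, and the bins at 32925001 and 32900001 lay 167180 and 142180 bp from the gene. The next bins were at Cyrib (6.95 kb), Ubl7 (6.42 kb), Tex2 (5.31 kb), Adam19 (4.89 kb), Sema7a (4.79 kb) and Gatad2a (4.70 kb). In the other direction, the greatest excess of KO over WT was at Rhoh (13.3 kb), which encodes a small GTPase of blood cells. Other bins among the 10 with the greatest KO excess were at Ms4a6c (11.1 kb), Cd200 (10.5 kb), a bin 10974 bp from Cd5 (10.2 kb), Ubr4 (10.1 kb), Hif1a (10.0 kb), Satb1 (9.41 kb) and Aebp2 (9.35 kb). Both KO libraries exceeded both WT libraries in 7685 of 18104 bins with a peak, and both WT libraries exceeded both KO libraries in 1564.

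The second comparison asked which H3K27ac regions were called in a single genotype. Of 36466 merged regions, 16043 were called in all 4 libraries, 985 in both WT and neither KO library (WT-only), and 2588 in both KO and neither WT library (KO-only). Runx1, a transcription factor gene of T cell development, had 4 WT-only and no KO-only regions, the most WT-only regions among the 213 genes of the lists. Ets1 followed with 3, and Etv6, an ETS family repressor gene, had 2 WT-only beside 6 KO-only regions. Genes with a single WT-only region included Cd3e, Entpd1, Havcr2, Runx3, Tal1, Ccl4 and Crtam. Among the same genes, KO-only regions were most numerous at Bach2, a repressor gene of resting lymphocytes, with 9 of its 62 regions. The ETS family gene Elk3 had 5 of 19. Ptprc (of 24 regions), Satb1 (26), Il12rb2 (18), Nfkb1 (30) and Cd28 (14) had 4 each. Over all genes 6.57% of regions, counted per gene, were KO-only, and a gene with more regions can hold more of them.

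The covered lengths at the genes that follow did not overlap between the genotypes, which their choice by KO-only or WT-only regions favours. Over all genes with a region, both KO libraries were higher in 54.0% and both WT libraries in 6.37%. Not every named gene followed its regions, since Cd3e, with a WT-only region, had 3.23 and 3.22 kb in WT against 3.54 and 3.48 kb in KO. With 10 kb flanks, H3K27ac covered 14.7 and 14.4 kb of Satb1 in WT against 37.4 and 33.8 kb in KO. At Il12rb2, the gene of an IL-12 receptor chain, it covered 4.31 and 5.65 kb in WT against 19.4 and 13.9 kb in KO, and at Cd28, the costimulatory receptor gene, 7.73 and 5.27 kb against 20.6 and 17.4 kb. At Bach2 the lengths were 63.3 and 66.6 kb in WT against 87.5 and 85.1 kb in KO. Runx1 lay the other way, with 9.5 and 10.9 kb in WT against 7.43 and 9.04 kb in KO, as did Entpd1, with 3.23 and 2.44 kb against 1.54 and 1.58 kb.

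**Figure D3:**
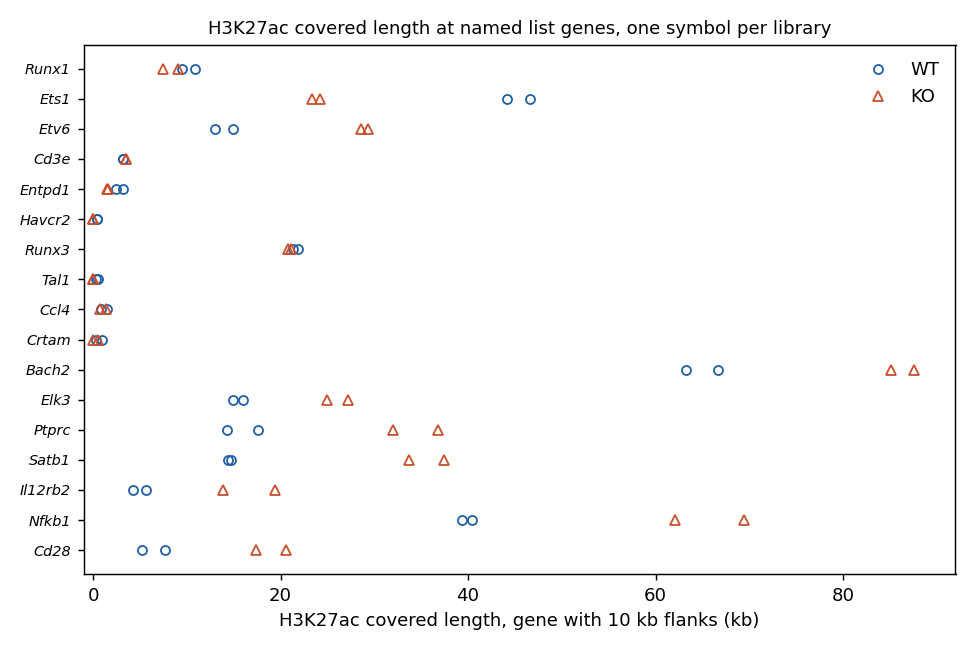
H3K27ac covered length (horizontal axis, kb) over each gene with 10 kb flanks, for genes named from the lists by their number of WT-only or KO-only regions. Blue circles are the 2 WT libraries and orange triangles the 2 KO libraries. Ets1 lay higher in WT, with 46.6 and 44.1 kb against 24.2 and 23.4 kb in KO, and Nfkb1 higher in KO, with 69.4 and 62.0 kb against 40.4 and 39.4 kb in WT.

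The WT-only H3K27ac regions with the best ranks in their lists lay within Tnrc6c and Brf1, followed by 2 of the regions beyond Ets1, from 32909220 to 32913566 and from 32931136 to 32935106. Then came regions within Iqsec1, Babam2, St6galnac5, Runx1 and Irf2 and one 54149 bp from Lrpprc. The best-ranked KO-only regions lay near Psd2 and Klrb1c and within Pla2g15, Washc2, Stat4, Nek7, 1700030J22Rik, Erc1, Smc4 and Kcna2. Most regions called in a single genotype were weak calls in at least 1 library. In the weaker of their 2 libraries, 92.4% of WT-only and 93.3% of KO-only regions ranked below the list's median, and 0 of either ranked in the top 10%. By the same measure 38.5% of the shared regions in WT and 31.6% in KO ranked below the median. Of the WT-only regions 11.8% had their midpoint within 2 kb of an end of a protein-coding gene, against 17.9% of the KO-only and 50.4% of the shared regions. In all, 3573 regions divided by genotype, against 1015 and 1019 in the mixed splits that pair a WT with a KO library. The mixed splits part the technical replicates of WT, which the split by genotype keeps together, so they can be lower without any effect of genotype. With the same number of top-scored peaks in each library the counts were 1295 WT-only and 1724 KO-only, so the share of KO-only among them was 57.1% in place of 72.4%. Leaving out a library loosens the definition. Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 in turn, there were 2901, 3069, 1491 and 1795 WT-only and 3928, 3824, 7057 and 5779 KO-only regions.

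**Figure D4:**
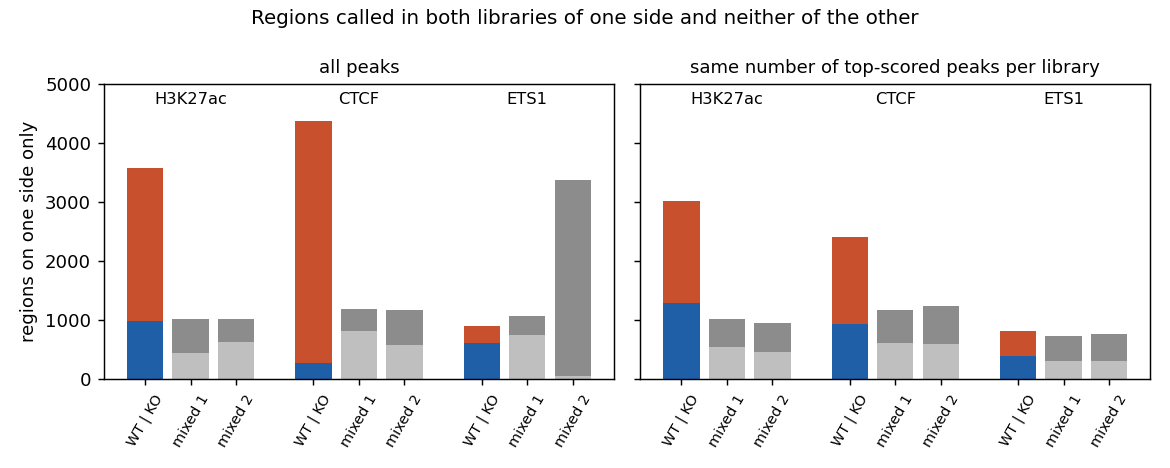
Number of regions (vertical axis) called in both libraries of a side and in neither of the other, for the split by genotype and for the 2 mixed splits of the same 4 libraries, with all peaks (left) and with the same number of top-scored peaks per library (right). Blue is WT-only, orange is KO-only and greys are the sides of the mixed splits, and the split by genotype stands highest for H3K27ac and CTCF but not, with all peaks, for ETS1.

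Gene lists fixed before the data were examined were compared by the H3K27ac covered length of each gene with 10 kb flanks. A list's median is taken over all its members, and a member without a peak counts as 0. The median over all genes below leaves such genes out. Over the 13281 protein-coding genes with a region, the median log2 ratio of KO to WT was 0.18, and both KO libraries exceeded both WT libraries in 54.0% of genes, where chance gives 16.7% for 4 independent libraries and more where the WT libraries share an animal. The naive and memory T cell genes stood above other genes, with a median of 0.64 that lay at the 99.5 percentile of 10000 random lists matched on covered length, and with both KO libraries higher at 9 of 10 genes. At Ccr7, a chemokine receptor gene of lymph node homing, H3K27ac covered 1.67 and 2.23 kb in WT and 9.26 and 9.93 kb in KO. At Lef1 it covered 19.9 and 17.6 kb against 31.9 and 31.3 kb, and at Tcf7 6.90 and 8.28 kb against 11.2 and 13.9 kb. Foxo1 was the exception, at 2.82 and 3.01 kb in WT against 2.82 and 2.83 kb in KO. This list had no WT-only and 15 KO-only regions of 110. Members other than Bach2 were picked as examples after their values were seen.

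By their median the Th1 genes stood below other genes, with a log2 ratio of 0.01 at the 0.24 percentile of matched random lists, whose median was 0.19. The list's median was 0.037 without WT replicate 2 and 0 without each other library in turn. It was 0.12 with 50 kb flanks (1.46 percentile). The median covers all 29 members, of which 25 had a region, and a member without a peak counts as 0. A median of 0 can thus fall on such members. Summed over the list, however, the covered length was 138 and 134 kb in WT and 199 and 183 kb in KO, so the sum lay higher in KO where the median did not. Of the 25 Th1 genes with a region, 10 had both KO libraries higher and 4 had both WT libraries higher. Tbx21, which encodes the Th1 master regulator T-bet, had 8.98 and 9.68 kb in WT and 10.8 and 8.88 kb in KO. Runx3 had 21.4 and 21.8 kb in WT and 21.1 and 20.8 kb in KO, and Gzmb, a cytotoxic granule protease gene, had 3.54 and 3.15 kb against 2.82 and 3.19 kb. Prf1, the perforin gene, had 0.903 and 0.661 kb in WT and no peak in KO, and Havcr2 had 0.374 and 0.398 kb in WT and no peak in KO. Il2ra, the gene of an IL-2 receptor chain, went the other way, with 10.8 and 10.0 kb in WT and 31.4 and 26 kb in KO, together with Il12rb2. Ifng had a peak in WT replicate 1 alone, over 0.727 kb. Tbx21, Gzmb, Prf1, Il2ra and Ifng were picked as examples after their values were seen. The list held 4 WT-only and 12 KO-only regions of 135 (69.8 and 78.5 percentiles). In windows of 5 kb at gene ends it held 4 WT-only and 3 KO-only of 62 (99.0 and 36.7 percentiles).

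Other T cell lists had higher medians. The Tfh genes stood at 0.53 (97.8 percentile), the Th2 genes at 0.30 (98.2 percentile), the Th17 genes at 0.19 (95.1 percentile) and the Treg genes at 0.26 (71.8 percentile). Without WT replicate 1 the Th17 median was 0.10 and the Treg median 0.59. With 50 kb flanks the Tfh, Th2 and Th17 genes lay at the 91.7, 92.9 and 92.5 percentiles. The T cell activation genes had a median of 0.36 (70.4 percentile) and the T cell identity genes 0.29 (20.9 percentile), although their members Satb1, Cd28 and Ptprc were among the genes with the most KO-only regions and the list's 23 KO-only of 201 regions lay at the 95.8 percentile (97.0 with the same number of peaks per library, 74.8 with windows of 5 kb at gene ends). The housekeeping genes, which serve as a reference, also lay high, at 0.48 (99.6 percentile), with both KO libraries higher at 16 of 18, but at the 86.4 percentile with 50 kb flanks. The ETS family genes stood at 0.24 (63.6 percentile). Their 21 KO-only regions of 128 lay at the 99.5 percentile of random lists matched on the number of regions. With the same number of peaks per library they held 12 of 116 (97.5 percentile), and in windows of 5 kb at gene ends 4 of 31 (93.8 percentile). The Ets1 locus genes had 5 WT-only regions of 37, at the 99.4 percentile, and none in windows of 5 kb at gene ends. Of 16 lists with a region, 5 lay above the 95th and 1 below the 5th percentile for covered length.

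Few markers of other cell types had an H3K27ac peak near a gene end. H3K27ac peaks lay within 2 kb of an end of 20 of 20 T cell identity genes in each of the 4 libraries, and of 0 of 5 NK cell markers. They lay near 2 and 3 of 8 B cell markers in WT and 2 and 2 in KO, and near 3 of 10 myeloid markers in each library. The counts were 1 of 3 CD8 T cell markers in each library, 2 and 1 of 5 erythroid markers in WT and 1 and 2 in KO, and 0 of 10 non-haematopoietic genes. Of 29 Th1 genes, 22 had such a peak in each WT library and 19 in each KO library. Summed with 10 kb flanks, H3K27ac covered 7.33 and 5.60 kb of the B cell markers in WT and 10.8 and 11.6 kb in KO, and 11.7 and 9.91 kb of the myeloid markers in WT and 12.3 and 14.9 kb in KO.

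The same comparison was made for CTCF, to see whether sites of this architectural protein differed. Of 47584 CTCF regions, 25226 were called in all 4 libraries, 276 were WT-only and 4095 were KO-only. No WT-only region lay at any gene of the lists with all peaks and 10 kb flanks. In lists of equal number the naive and memory T cell genes held 4 WT-only and 1 KO-only of 40 regions (99.6 and 43.5 percentiles) and the T cell identity genes 4 WT-only and 6 KO-only of 86, and with 50 kb flanks the Th1 genes held 3 and the Th2 genes 2 WT-only regions. Among the list genes, KO-only regions were most numerous at Runx1 (5 of 12 regions) and Nfkb1 (4 of 12). Ebf1 (of 14 regions), Etv6 (9), Nfatc1 (10) and Il12rb2 (4) had 3 each. Over all genes 8.65% of regions, counted per gene, were KO-only. Genes with 2 included Arhgap32, Ikzf1, Stat3 and Cd2. At Runx1, CTCF covered 2.72 and 3.68 kb in WT and 5.41 and 5.23 kb in KO, and at Ikzf1, a zinc finger factor gene of lymphocyte development, 0.337 and 0.645 kb against 2.28 and 2.60 kb. The T cell identity genes held 18 KO-only of 114 regions, at the 98.3 percentile of random lists, and the ETS family genes 11 of 67, at the 97.4 percentile. The Ets1 locus genes held 6 of 47, at the 79.6 percentile, among them 2 at Fli1.

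The best-ranked WT-only CTCF regions lay within Scn8a, Stoml3, Agps, Tmod3 and Dnah12 and near Cyct, Mndal, Bsph1, Lrrc8c and Zfp518b. The best-ranked KO-only CTCF regions lay within Ptch1, Ppp1r42, Fbxw7, H6pd, Ptk2b, Nhsl1 and 2510002D24Rik and near Bmpr2, Slc16a1 and Golim4. The split by genotype gave 4371 regions on a single side, against 1194 and 1166 in the mixed splits. The CTCF lists shared 58.8% of their joint length in the WT pair, 68.0% in the KO pair and 56.2% to 58.4% across genotypes. With the same number of peaks these values were 59.5%, 69.0% and 59.1% to 60.9%, so the WT pair was then no more alike than libraries of different genotype. Of the KO-only regions 95.9% ranked below the median in the weaker of their 2 libraries, against 34.8% of the shared regions in KO. With the same number of top-scored peaks per library the counts were 936 WT-only and 1466 KO-only, a KO-only share of 61.0% in place of 93.7%, and the KO-only percentage was 6.98% in place of 15.8% in the T cell identity list and 1.82% in place of 16.4% in the ETS family list, at the 93.4 and 27 percentiles. Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 in turn, there were 1353, 2333, 751 and 581 WT-only and 7001, 6537, 7036 and 7765 KO-only regions.

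For ETS1, 54969 merged regions held 6533 called in all 4 libraries, 618 WT-only and 285 KO-only. Ets1 itself had the most WT-only ETS1 regions, with 2, and covered lengths with flanks of 3.23 and 9.31 kb in WT against 2.58 and 2.13 kb in KO. Genes with a single WT-only region included Etv6, Cd4, Foxo1, Actb, Lck, Myc, Tnf, Crtam and Ikzf1. At Tnf, an inflammatory cytokine gene, ETS1 covered 3.31 and 3.93 kb in WT and 2.29 and 1.33 kb in KO, and at Myc 2.68 and 3.45 kb against 2.00 and 1.94 kb. Satb1 had 2 KO-only ETS1 regions, Bcl11b, Nr4a1 and Batf had 1 each, and Eomes had 1 KO-only and 1 WT-only region. The Th1 genes held 6 WT-only of 99 regions, at the 99.96 percentile of random lists, and the T cell identity genes 6 WT-only and 4 KO-only of 180, at the 98.1 and 99.4 percentiles. The Ets1 locus genes held 3 WT-only of 47, at the 99.3 percentile. With the same number of peaks per library, the Th1 genes held 1 WT-only of 42 regions (54.2 percentile), the Ets1 locus genes 0 of 12, and the T cell identity genes 5 WT-only (96.3 percentile) and 0 KO-only of 80 (7.54 percentile). The T cell identity genes also held 0 KO-only regions in windows of 5 kb at gene ends.

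The best-ranked WT-only ETS1 regions lay within Ctif, Ndufb3, Prkacb, Tnrc6a, Zfp418, Mtmr6 and Por and near Ptbp1, Il12a and Sema4d. The best-ranked KO-only ETS1 regions lay within Nhp2, Mtrf1, Auh, Parp1, Rasgrp1, Olfr646 and Rab39b and near Rgs3, Olfr545 and Fam111a. The genotype split did not stand out for ETS1, since 903 regions divided by genotype against 1073 and 3376 in the mixed splits. With the same number of top-scored peaks per library the numbers were 809 against 727 and 765, with 393 WT-only and 416 KO-only regions. Without WT replicate 1 there were 9919 WT-only regions, without WT replicate 2 there were 4240, and without KO replicate 1 there were 2648. KO-only regions numbered 26621 without KO replicate 2, 1280 without WT replicate 2 and 1034 without KO replicate 1. The lists also overlapped less than those of H3K27ac, at 32.5% of the joint length for the WT pair and 22.3% for the KO pair, against 65.3% and 66.3% for H3K27ac. The ETS1 lists differ greatly in length, and at equal number the ETS1 values were 43.3% and 40.6%, with 41.2% to 46.0% across genotypes, against 65.4% and 67.5% for H3K27ac.

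The overlap of ETS1 with the other antibodies was examined next. Of 9312 regions called in both WT ETS1 libraries, 85.1% (exact 95% interval 84.3 to 85.8) overlapped an H3K27ac region called in both WT libraries, against a mean of 1.81% after 100 random placements on the same chromosomes. CTCF regions were overlapped by 70.9% (70.0 to 71.8), against 1.90% after placement. Among regions called in either WT ETS1 library the shares were 46.1% and 37.1%, and without WT replicate 1 they were 52.1% and 41.4%. In KO, 91.3% of 7881 ETS1 regions overlapped H3K27ac and 92.1% overlapped CTCF, but without KO replicate 2, which leaves the longest ETS1 list, the shares were 33.5% and 35.9%, and without KO replicate 1 they were 85.2% and 83.9%. Of the ETS1 regions shared by all 4 libraries, 82.1% lay near a gene end. The intervals cover counting error only. Of the 285 IgG peaks in KO, 72.3% overlapped WT H3K27ac regions and 72.6% WT CTCF regions. Their shares with the KO regions were 76.5% and 82.5%. The contrast with random placement is therefore not particular to ETS1.

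It was then examined whether the H3K27ac regions called in a single genotype lay at ETS1 sites. Of the shared H3K27ac regions 47.5% overlapped an ETS1 region called in both WT libraries, against 5.18% of the WT-only and 5.80% of the KO-only regions. The last pair of shares did not differ by Fisher's exact test across regions (two-sided p = 0.516), which are not independent replicates. With the ETS1 regions of the KO libraries the shares were 1.73% of the WT-only and 4.29% of the KO-only H3K27ac regions (exact p = 1.1e-04). For CTCF, 5.43% of the WT-only and 15.8% of the KO-only regions overlapped a WT ETS1 region (Fisher's exact p = 3.5e-07), against 26.2% of the shared regions. The KO-only CTCF regions also lay near a gene end more often than the WT-only regions, at 30.5% against 10.1%, and the overlap was not matched on location.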

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

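The tests of the shift of other tiles, of the missing DNA and of list length were chosen after their results had been seen; the others were set down beforehand. The IgG library of the KO genotype had 285 peaks against 2 in WT, and drew attention because the peak lists of a control antibody differed in length between the genotypes, with 1 library each. Of these peaks 82.5% overlapped a CTCF region called in both KO libraries, against 1.52% after random placement, and 76.5% overlapped such an H3K27ac region, against 1.58%.

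H3K27ac calls were missing at Ets1 in both KO libraries. Fewer or shorter calls throughout the KO lists cannot account for this, since the median log2 ratio of the other 2 Mb tiles was 0.37, opposite in sign to the -1.25 of the window. Loss of DNA reaching through the last lost region, which ends at 32943055, is argued against by CTCF peaks that overlapped lost regions in 2 of 2 KO libraries. Loss of DNA in the 34.2 kb before the first retained CTCF region (32906098 to 32940264) cannot be told apart from loss of acetylation. The 6 KO libraries had 0 peaks there, but no CTCF or ETS1 region there was called in both WT libraries. Peak lists also do not show reads. The longer stretch without a KO peak, from 32746522 to 32940318, holds an ETS1 region called in both WT libraries, from 32750074 to 32750555. The outcome thus depends on the interval chosen, and loss of DNA over the whole stretch was not tested. The strain label places the knocked-out element at Ets1 without coordinates, so the missing calls may be the engineered change itself. A biological loss of acetylation in the altered strain also stays open and was not tested.

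ETS1 replicate 1 of KO had 40705 peaks against 9344 to 23419 in the other ETS1 libraries, and 26303 of its regions were private to it. Background calls away from acetylated sites were set to require under 10% of the private regions at H3K27ac, with over 30% against, and the value was 10.1% (exact 95% interval 9.71 to 10.4), against 76.3% of its other regions. The private regions of WT replicate 1 gave 8.98% and those of KO replicate 2 gave 33.1%. Weak calls from a longer list required at least 75% of private regions below the list's median rank, with under 50% against, and the value was 66.9%. Neither value cleared its bounds, so background and weak binding cannot be told apart, and a biological difference between the KO animals stays open and was not tested.

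CTCF regions called in KO only outnumbered those called in WT only by 4095 to 276. With the same number of peaks per library the KO-only share was 61.0% in place of 93.7%. Equal numbers of peaks would lower this share after a true gain of sites as well. The test therefore cannot tell longer KO lists from gained sites. Cutting at acetylated open chromatin in the KO libraries was set to require at least 10 percentage points more overlap with H3K27ac among KO-only than among shared CTCF regions. The difference was 6.22 points (41.6% against 35.3%), which leaves it open. Shared regions were also wider, at a median of 734.5 bp against 351 bp, and wider regions overlap others more readily. The shares were not matched on width. A biological gain of CTCF sites in KO also stays open and was not tested.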

How the results depend on the processing

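Tests of gene lists by covered length, under each setting, and of the ETS1 overlap without a library or for regions called in either KO library were chosen after the data were examined. No paired analysis was possible because by the titles the replicate numbers mark technical replicates in WT and biological replicates in KO, and presence calls come from no fitted model. The H3K27ac log2 ratio of the Ets1 window kept its direction by number of peaks, with the same number of peaks per library and without each library in turn (-1.27 to -1.23 in the last). An overlap of at least 50%, merging up to 500 bp and removal of IgG-overlapping peaks left all 6 counts within 1.5 times, and 50 kb flanks left the list percentages examined within their wide exact intervals, although the Treg KO-only percentage of H3K27ac was 11.1 in place of 3.92 (91.3 in place of 27.9 percentile). By covered length, 50 kb flanks gave H3K27ac medians of 0.12 (Th1), 0.39 (Th2), 0.32 (Th17), 0.37 (T cell identity), 0.53 (naive and memory) and 0.42 (housekeeping). Motifs over whole peaks were not run, since no genome was used here, and windows at both gene ends replaced windows at transcription starts, for want of strand. Depth is unknown, so list length limits each count. Except where the construction of the alternative shows it, the cause was not tested.

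The same number of peaks gave 1724 H3K27ac KO-only, 936 and 1466 CTCF WT-only and KO-only, and 393 ETS1 WT-only regions, and a CTCF ratio of 0.10 in the window. In lists, it gave KO-only percentages of 0 (Th2) and 10.3 (ETS family) for H3K27ac, 4.17 (Th1), 6.98 (T cell identity) and 1.82 (ETS family) for CTCF, and 0 (Th1, T cell identity) for ETS1, CTCF WT-only percentages of 4.65 (T cell identity) and 10 (naive and memory) in place of 0, an ETS1 WT-only percentage of 0 (Ets1 locus), and H3K27ac medians of 0.26 (Th2), 0.32 (activation) and 0.40 (housekeeping). The top-scored 50% of each list, which holds fewer peaks, gave 373 and 1031 H3K27ac WT-only and KO-only, 2073 CTCF KO-only, and 257 and 140 ETS1 WT-only and KO-only regions. Windows of 5 kb at gene ends gave H3K27ac WT-only percentages of 0 (Ets1 locus, Treg, activation, ETS family) and 1.64 (T cell identity), KO-only percentages of 0 (Ets1 locus, Th2), and an ETS1 KO-only percentage of 0 (T cell identity).

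By number of peaks the window's ratio was -0.38 for H3K27ac and 0.29 for CTCF. Of the 10 top WT-higher bins, 7 lay in the window with 10 kb and 2 with 50 kb bins. Of ETS1 regions called in either WT library 46.1% overlapped H3K27ac and 37.1% CTCF, and with equal numbers 91.7% and 77.6%. For KO these shares were 34.0% and 36.0%, and 95.6% and 96.1%. Windows of 1 kb placed 44.1%, 7.01% and 12.1% of shared, WT-only and KO-only H3K27ac regions, 28.6%, 5.43% and 24.7% of CTCF and 76.1%, 15.5% and 36.8% of ETS1 regions near gene ends.

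The extremes of the region counts without a library, which loosens the definition, came without KO replicate 1 (1491 WT-only and 7057 KO-only) and WT replicate 2 (3069 and 3824) for H3K27ac, without KO replicate 2 (581 and 7765) and WT replicate 2 (2333 and 6537) for CTCF, and without WT replicate 1 (9919 and 398) and KO replicate 2 (778 and 26621) for ETS1, as WT-only and KO-only counts. The window's ratio ranged from 0.35 to 0.53 for CTCF and from -1.61 (without KO replicate 1) to -0.20 (without WT replicate 2) for ETS1. H3K27ac list medians ranged from 0 to 0.037 (Th1), 0.22 to 0.30 (Th2), 0.10 to 0.28 (Th17), 0.19 to 0.59 (Treg), 0.51 to 0.65 (Tfh), 0.28 to 0.33 (T cell identity), 0.52 to 0.74 (naive and memory), 0.33 to 0.39 (activation), 0.23 to 0.27 (ETS family) and 0.43 to 0.57 (housekeeping). In WT the ETS1 overlap ranged from 52.1% to 62.3% for H3K27ac and from 41.4% to 52.0% for CTCF, and in KO from 33.5% (without KO replicate 2) to 85.2% and from 35.9% to 83.9%.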

Other observations

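The values here were picked after the data were examined. Among stretches of the genome without a WT peak of any antibody, ranked by the lower KO H3K27ac length, the first lay nearest to Clec2d, a lectin gene, with 4277 bp in both KO libraries on chromosome 6 from 129185530 to 129189806. Other high-ranked stretches lay nearest to Rasgrp1 (4115 and 5432 bp), an activator of Ras in T cells, Cd226 (5168 and 3798 bp) and Dusp4 (4460 and 3745 bp). These lengths are below the 25692 bp of the stretch at Ets1 in the opposite direction. Over Cd226, an activating receptor gene of T and NK cells, with 10 kb flanks, H3K27ac covered 1.73 and 2.82 kb in WT and 15.3 and 10.6 kb in KO. Over Cyrib it covered 26.1 and 23.5 kb in WT and 16.7 and 16.2 kb in KO.

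For ETS1, the 25 kb bins with the greatest WT excess lay at Laptm5 (2.57 kb), Akna (2.47 kb), Vav1 (2.29 kb), Csrnp1 (2.27 kb), Trir (2.16 kb) and Stat5a (2.08 kb). WT replicate 2 carried much of this, and without it the excess was 1.2 kb at Laptm5, 1.21 kb at Akna, 0.987 kb at Vav1, 1.33 kb at Csrnp1, 1.13 kb at Trir and 1.5 kb at Stat5a. Without WT replicate 1 it was 3.94, 3.73, 3.6, 3.21, 3.19 and 2.66 kb in the same order. Without KO replicate 2 it was 1.49 kb at Akna and 1.21 kb at Csrnp1. Vav1 and Stat5a encode signalling proteins of T cells. For CTCF, the bins with the greatest KO excess lay at Acot7 (3.34 kb), Irf2bpl (3.25 kb), Ppp1r35 (3.19 kb), Hdac7 (3.18 kb) and Junb (3.12 kb).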
